A study of Mus musculus with 6 samples.

How the data were processed

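RNA was measured by sequencing in 6 libraries of mouse cortical neurons of CD1, an outbred stock. The labels put them in 3 groups of 2, a control, PA and PA + PS2, each with a repeat 1 and a repeat 2. The treatment label reads peptide amphiphile for all 6 libraries, the control included. Library names carry PDL for the control, IKVAV (a laminin-derived peptide sequence) for PA, and IKVAV with PEDOT-S (PEDOT is a conducting polymer) for PA + PS2; PS2 itself is not spelled out in the sources used here. Culture time, plating and dose are not given in the sources used here. RNA was extracted with an RNeasy micro kit and libraries were made with a TruSeq Total RNA kit, per the labels' protocols, whereas the molecule label names polyadenylated RNA. Strandedness is not given in the sources used here, so genes that overlap an antisense partner are uncertain.

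The deposited values are raw counts per Ensembl gene, per the file headers and their whole-number values, with 1 library per file and no rows of unassigned reads. The submitters' processing notes name cutadapt 4.2, STAR 2.7.5, HTSeq 2.0.2, DESeq2 1.14.1 and the mm10 build, without roles or settings. Trimming, alignment and counting settings, the annotation release and any filters are not given in the sources used here. Each file lists 54232 genes, of which 153 had no symbol in the reference used here. Coordinates were taken from GENCODE M21 on GRCm38, the assembly also called mm10, and 54165 of the gene identifiers had coordinates there.

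Library totals ran from 30714311 counts (PA 1) to 33923681 (control 2), so 1 CPM (count per 1e6 counts) stands for 30.7 to 33.9 counts. In each library 23667 to 25190 genes had at least 1 count. Replicates of a group differed far beyond sampling noise (chi-square per degree of freedom 14.6 to 21.1), so none was treated as a library deposited more than once. The labels do not say whether repeats were separate cultures or animals, so p-values measure only the spread between these samples. The Y-linked Ddx3y was at 16.9 to 18.5 CPM in repeat 1 and 36.2 to 39.5 in repeat 2. Eif2s3y was also higher and Xist lower in repeat 2 in all 3 groups. These sex-linked genes argue against a purely technical difference between the repeat numbers. The spread that remains with the repeat number in the model may be technical. The median standard error of a log2 fold change for PA + PS2 versus control was 0.66 for genes under 1 CPM, 0.37 at 1 to 5 CPM, 0.19 at 5 to 20 CPM, 0.11 at 20 to 100 CPM and 0.08 above 100 CPM.

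Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, robust quasi-likelihood F test, 1 model over all 6 libraries with 3 residual degrees of freedom). The filter left 17299 genes, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Standard errors were derived from the log2 fold change and the F statistic. CPM values are TMM-scaled. The biological coefficient of variation was 16.7%, and 9.6% with the repeat number in the model. Gene lists (35 lists of pathway and cell type genes) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with an estimated correlation and with fry as alternatives, adjusted over the 35 lists. The groups, the main model, the 35 lists, the rule for named genes and the alternatives listed in the next paragraph were fixed before the data were examined.

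The alternatives were RLE size factors, library totals alone, no filter, a filter of at least 50 counts in 2 libraries, DESeq2 1.42.0, limma-voom, edgeR's legacy quasi-likelihood, only the 2 groups compared, a minimum absolute log2 fold change of 1, the repeat number as a block, and leaving out each library in turn. Added after seeing the data were combinations of the block with DESeq2, limma-voom, the stricter filter, RLE, the 2 groups alone, each library left out, the estimated correlation and fry. Comparisons that share a group were set beside 50 simulations of unchanged groups.

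Whether the repeat numbers pair the libraries was decided from the correlation of same-numbered deviations, before the calls of the fits were compared. Repeat 1 minus repeat 2 differences correlated at 0.35 between control and PA, 0.36 between control and PA + PS2 and 0.21 between PA and PA + PS2, and the leading principal component separated the numbers. With 2 libraries per group there are only 2 pairs per comparison, and the rule was read over the 3 pairs of groups; the pairing therefore comes from the data, as the labels give no shared litter, batch or day. Library names carry a T number that is the same (T1) in all repeat 1 libraries and differs among the repeat 2 libraries. The block leaves 2 residual degrees of freedom. Its values are given beside each gene count and list shift it changed.

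Named genes were, per comparison, up to 8 with the highest and 8 with the lowest log2 fold change among genes past the threshold with a mean of at least 5 CPM, both libraries of one group above both of the other, and a symbol that is not a predicted-gene, Rik, pseudogene or mitochondrial name. If fewer than 4 qualified, the 6 with the smallest unadjusted p were named as not having passed. Added to these were up to 4 members with the smallest p of each shifted list and up to 2 called members of other lists, to about 30 names, and Map2, Tubb3, Rbfox3, Syn1, Dlg4, Fos, Bdnf, Itgb1 and Gfap throughout. Because the model without the block made no calls, the rule for genes past the threshold was also applied to the blocked fit, a step added after seeing that result. All other genes named, such as further called members of the lists (Nes, Notch1, Cd44, Mag and Mobp among them), were chosen after their values were seen. Results for items withheld for evaluation were left out.

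The scripts were tested on simulated counts built on the real means and library sizes for PA + PS2 versus control, with 200 changed genes. With a repeat effect in 16749 genes, the model without a block recovered 20% of genes changed 1.5-fold, 50.7% changed 2-fold and 78.7% changed 4-fold, with 0 false among 107 calls. The blocked model recovered 68%, 80% and 93.3%, with 6.82% of 176 calls false, and DESeq2 recovered 48%, 69.3% and 90.7%, with 2.7% of 148 calls false. These counts were drawn from the blocked fit with 1 repeat effect shared by all groups, so the blocked model was correct by construction. In the real libraries the repeat differences correlated at 0.21 to 0.36 between groups. The 6.82% therefore does not give the false share among the real calls with the block. Without a repeat effect, edgeR recovered 62%, 78.7% and 94.7%, with 9.04% of calls false, above the nominal rate. A list moved by 0.5 on the log2 scale was recovered by camera (adjusted p = 1.14e-55), by camera with an estimated correlation (adjusted p = 0.0137) and by fry (adjusted p = 0.0038), with 0 of the 34 other lists called. Apart from the repeat effect the simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.91. The simulation therefore does not show how these list tests perform on lists so correlated.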

Results

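Cortical neurons from CD1 mice were profiled in a control condition, with a peptide amphiphile (PA) and with PA plus PS2, in 2 libraries each. The title of the study names conductive and bioactive scaffolds and neuronal maturation. The 3 comparisons ask what PA changed, what PA with PS2 changed, and what PS2 added to PA. The libraries held 33291775 and 33923681 counts in the control, 30714311 and 31819918 in PA, and 31591670 and 30752495 in PA + PS2. Mitochondrial genes took 1.94% and 1.58% of counts in the control, 1.28% and 1.78% in PA, and 1.60% and 1.20% in PA + PS2. Levels are given in CPM (counts per 1e6 counts) with the SD over n = 2 libraries, and coordinates are on GRCm38.

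The libraries were separated by repeat number and by PS2. The leading principal component held 33.5% of the variance and scored -31.0, -19.7 and -33.5 in the repeat 1 libraries of control, PA and PA + PS2. The repeat 2 libraries scored 25.9 or more. The next component held 29.5% and scored -16.3 and -51.4 in PA + PS2, and lay above 0 in the other 4 libraries.

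**Figure D1:**
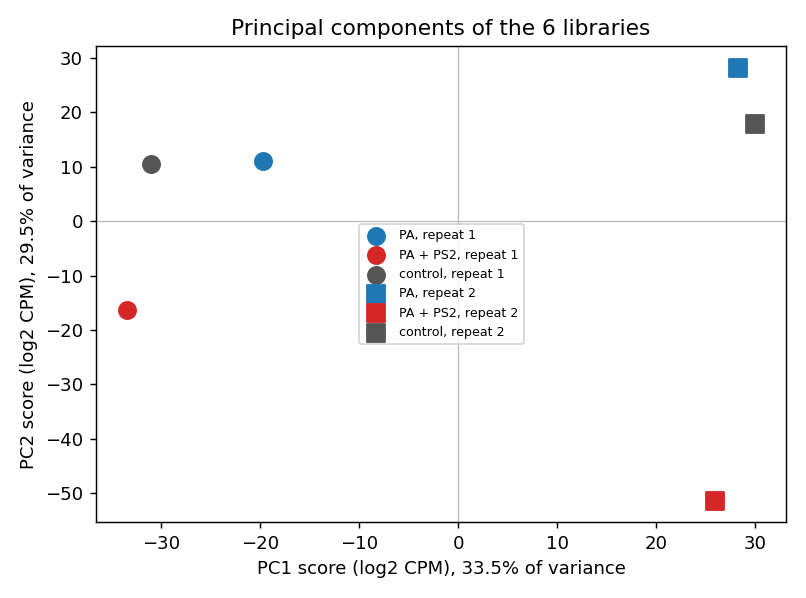
Scores of the 6 libraries on the leading principal components of log2 CPM, with the share of variance on each axis; colours are groups, circles repeat 1 and squares repeat 2. Repeat 1 libraries lie left of 0 and repeat 2 libraries right of it, and the PA + PS2 libraries lie at -16.3 and -51.4 on the vertical axis.

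With PA alone, neuronal genes lay close to the control. Map2, a dendritic microtubule protein, was at 2278 ± 160 CPM (SD, n = 2) in PA and 2317 ± 176 in the control. Tubb3, neuronal tubulin, was at 1707 ± 30.3 and 1708 ± 106 CPM, and Syn1, a synaptic vesicle protein, at 435 ± 15.2 and 426 ± 28.3 CPM. The immediate early gene Fos was at 65.4 ± 8.72 and 62.3 ± 1.84 CPM, the neurotrophin gene Bdnf at 67.7 ± 13.6 and 66.0 ± 2.32 CPM, and Itgb1, an integrin beta subunit, at 125 ± 5.85 and 121 ± 16.3 CPM. Rbfox3 and Dlg4 had log2 fold changes of -0.02 and -0.02, and Gfap, an astrocyte filament gene, was at 0.792 ± 0.800 and 0.313 ± 0.400 CPM; none of these genes passed the test.

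No gene passed between PA and control in edgeR's quasi-likelihood test (0 of 17299, smallest adjusted p = 1.00). At an unadjusted p under 0.05 there were 138 genes, where 865 are expected by chance. So large a deficit means that the test was conservative here, and it is not evidence that PA changed nothing. Without the block the repeat difference counts as residual spread (biological coefficient of variation 16.7%, and 9.6% with the block). DESeq2, limma-voom and the legacy test called 0, and edgeR with the repeat block called 0 with 323 genes at unadjusted p under 0.05; the block in DESeq2 called 1, Lars2, which fell (adjusted p = 0.0432). With the block, 8 genes passed with only the 2 groups compared, 10 without PA 1 and 12 without PA 2. The 6 genes with the smallest p, none of which passed in edgeR, began with Lars2, a mitochondrial leucyl-tRNA synthetase, at 118 ± 19.5 CPM in PA and 171 ± 10.2 in the control. They went on with Slc7a3, a cationic amino acid transporter (19.1 ± 1.39 and 13.0 ± 1.48 CPM), Prickle1 (40.2 ± 0.533 and 31.8 ± 0.249 CPM) and Haus6 (16.4 ± 0.0826 and 12.2 ± 0.465 CPM). Chac1 was at 22.2 ± 2.00 and 17.1 ± 0.823 CPM and Camkmt at 6.57 ± 0.572 and 4.32 ± 0.126 CPM. Lars2 fell when adjusted over the list alone, in a list of histone and structured RNA genes that was not itself shifted. That list was set up as a measure of RNA quality, and whether the Lars2 change reflects RNA quality was not tested.

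Of 35 gene lists, 8 were shifted between PA and control by camera, 5 upwards and 3 downwards, and each had an adjusted p = 0.956 with an estimated correlation. The astrocyte list was shifted upwards (median log2 fold change 0.56, 18 of 19 members above 0, adjusted p = 7.28e-05). Aqp4, a water channel, was at 2.19 ± 1.95 CPM in PA and 0.730 ± 0.232 in the control, and Apoe, a lipid carrier, at 15.6 ± 8.49 and 10.3 ± 0.631 CPM. None of the 19 members passed over all genes, and 3 (Aldoc, Aqp4 and Mlc1) rose with the block when adjusted over the list alone. The cell cycle list was shifted upwards (0.28, 26 of 27 above 0, adjusted p = 0.000792), with Mcm2, a replication helicase subunit, at 17.1 ± 4.38 and 13.1 ± 3.47 CPM and Bub1b at 7.47 ± 3.58 and 5.15 ± 2.40 CPM. Upward shifts were also called for the unfolded protein and integrated stress response (0.06, adjusted p = 0.00306) and cholesterol biosynthesis (0.07, adjusted p = 0.00441). The same held for TGF-beta, BMP and Wnt targets (0.10, adjusted p = 0.00534). Asns, for asparagine synthesis, was at 193 ± 7.83 and 175 ± 6.80 CPM, Mvk, for mevalonate metabolism, at 59.5 ± 7.28 and 52.2 ± 3.45 CPM and Skil at 93.0 ± 3.55 and 84.6 ± 1.95 CPM. Mitochondrially encoded mRNA (-0.17, adjusted p = 0.00234), ribosomal proteins (-0.02, adjusted p = 0.0264) and extracellular matrix (-0.14, adjusted p = 0.0299) were shifted downwards. No member of the 7 lists other than the astrocyte list passed over all genes or adjusted over the list alone, with or without the block.

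The repeats differed for several of these lists. The mitochondrial list had a median of -0.58 in repeat 1 and 0.18 in repeat 2, and the matrix list 0.15 and -0.35. Each member was also set against its own mean over all libraries on the log2 scale. The median over members was then 0.93 in PA 2 and -0.05 in PA 1 for the astrocyte list, and 1.03 and 0.06 for the cell cycle list. Controls 2 and 1 had a gap as well, with 0.33 and -0.24 (astrocyte) and 0.67 and -0.10 (cell cycle). Within repeats 1 and 2 the medians of PA against the control were 0.31 and 0.69 (astrocyte) and 0.24 and 0.32 (cell cycle). The fits below that leave out a library do not use the block, so the repeat difference enters those without a PA or control library. Of the 8 lists, 4 kept their shift without PA 1, 3 without PA 2, 2 without control 1 and 6 without control 2, and 8 did without either PA + PS2 library. Without PA 2 the astrocyte, cell cycle, matrix, ribosomal and stress response lists lost it, and the cell cycle list was then shifted downwards. Without control 1 all but the matrix and ribosomal lists lost it, without control 2 those 2, and without PA 1 the cholesterol, mitochondrial, ribosomal and TGF-beta lists. With the block the progenitor list (0.19, block adjusted p = 0.000527) was shifted upwards as well, with Notch1 risen when adjusted over the list alone; it had an adjusted p = 0.927 with an estimated correlation and the block. Fry with the block called the stress response list (adjusted p = 0.0399) and no other.

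In PA + PS2, 4 of 34 matrix, 7 of 27 cell cycle, 2 of 25 integrin and focal adhesion and 3 of 28 activity-regulated genes fell against the control with the repeat block, and 0 without it in edgeR. The camera shifts of these 4 lists were lost with an estimated correlation (adjusted p = 0.321 to 0.322 with an estimated correlation). With the repeat block, Ccn1, a matricellular protein, fell to 10.2 ± 1.55 CPM (SD, n = 2) from 23.5 ± 1.66 (edgeR adjusted p = 0.0140), and Lamc1, a laminin chain, to 40.8 ± 1.57 from 61.7 ± 9.37 CPM. Cdk1, the mitotic kinase, fell to 1.67 ± 0.0224 from 7.10 ± 3.52 CPM, and Scg2, an activity-induced secretogranin, to 212 ± 43.3 from 355 ± 38.0 CPM. Itgb1, shared by several laminin-binding integrins, fell to 83.4 ± 0.0701 from 121 ± 16.3 CPM.

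Without the block, edgeR called 0 genes between PA + PS2 and control (smallest adjusted p = 0.270), with 1179 at unadjusted p under 0.05 where 865 are expected. The block called 117 (24 higher and 93 lower), DESeq2 130 (20 and 110, of which 79 shared with the block), and limma-voom and the legacy test 0. The block called 42 with a stricter filter, 279 in DESeq2 and 849 with only the 2 groups compared. With the block 0 genes passed without PA + PS2 2 or without control 2, 61 without control 1, 503 without PA 1, 522 without PA + PS2 1 and 560 without PA 2. Without the block 7 passed when PA + PS2 1 was left out. Map2 was at 2260 ± 0.0631 and 2317 ± 176 CPM, Tubb3 at 1788 ± 202 and 1708 ± 106 CPM, Syn1 at 412 ± 19.9 and 426 ± 28.3 CPM and Dlg4, a postsynaptic scaffold, at 447 ± 17.4 and 502 ± 17.5 CPM. None of these 4 passed, nor did Rbfox3 (log2 0.00) or Gfap, at 0.501 ± 0.348 CPM in PA + PS2.

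Among the genes called with the block and ranked by fold change, Fst, the activin antagonist follistatin (chromosome 13, 114452290 to 114458951), rose to 46.9 ± 6.63 from 21.1 ± 5.23 CPM. Nos1, neuronal nitric oxide synthase, rose to 82.0 ± 8.12 from 56.4 ± 1.44 CPM. Slc16a6, Hivep3, St6galnac5, Cdh4 and Foxred2 rose as well, with block log2 fold changes between 0.54 (Foxred2) and 0.72 (Slc16a6). Epas1, a hypoxia-inducible transcription factor (chromosome 17, 86753700 to 86833410), fell to 1.71 ± 0.0228 from 7.86 ± 1.05 CPM. Tagln2, Col18a1, Emp1, Loxl2, Anln and Tead2 fell, with block log2 fold changes between -1.98 (Tagln2) and -1.59 (Tead2). Fstl1, Adamts1, Peg10, Ptpn14 and Emp1, among the genes with the smallest p without the block in edgeR, did not pass there but passed with the block and in DESeq2 without it. Peg10, an imprinted gene, fell with the block to 216 ± 4.90 from 310 ± 12.4 CPM.

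**Figure D2:**
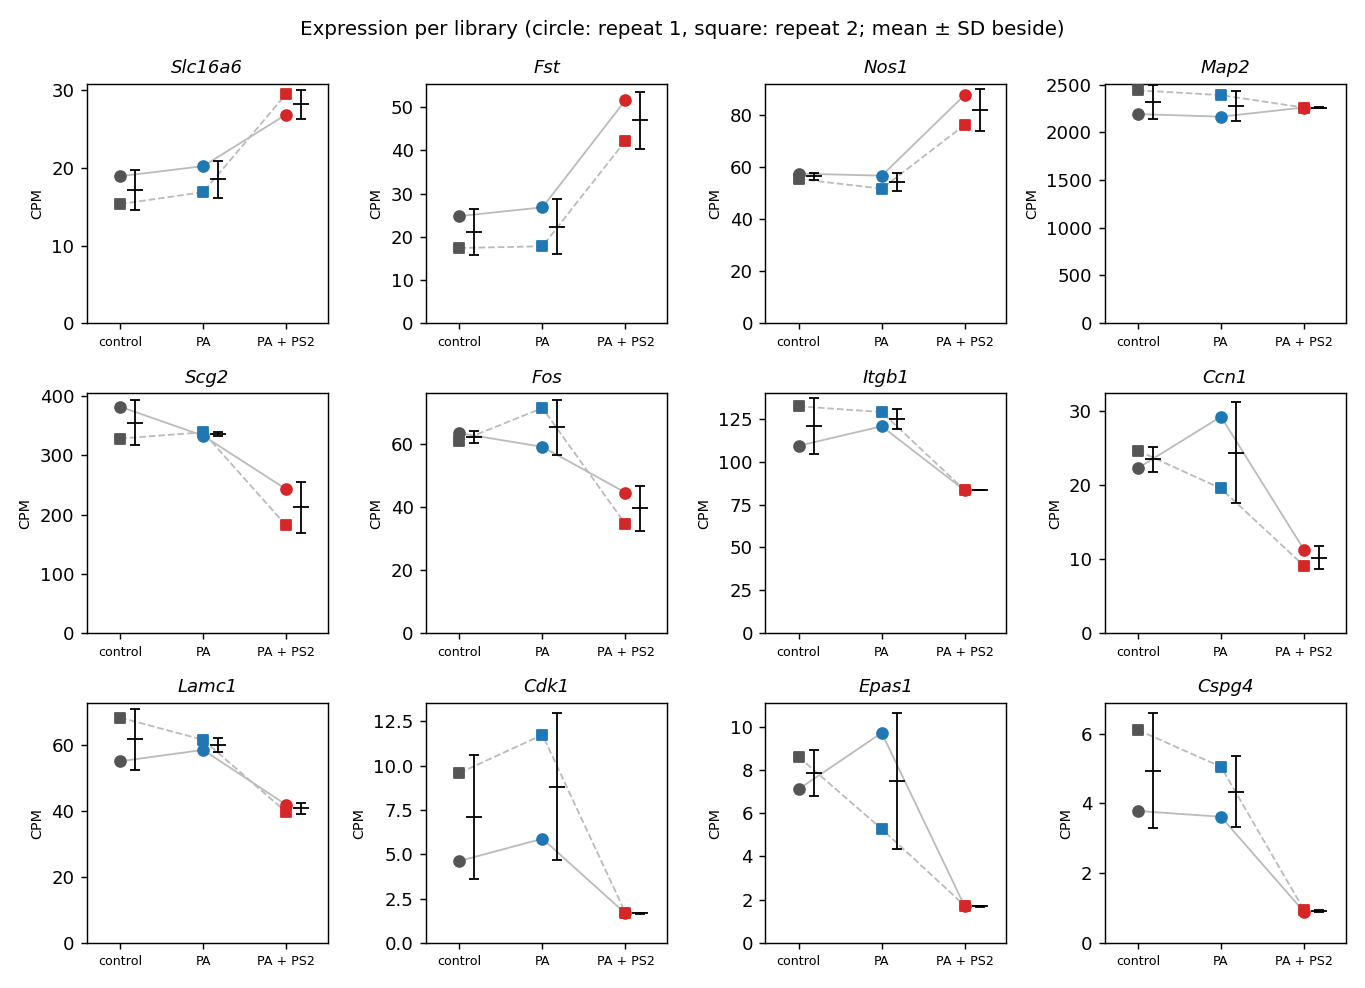
CPM of 12 named genes in each library (circle repeat 1, square repeat 2, lines join the same repeat; black bars show mean and SD of n = 2). Slc16a6, Fst and Nos1 lie higher in both PA + PS2 libraries, Map2 lies between 2165 and 2441 CPM in all 6, and the other 8 genes are lower in both PA + PS2 libraries than in both control libraries.

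Of the 35 lists, 23 were shifted in PA + PS2 against the control, 5 upwards and 18 downwards. None kept its call with an estimated correlation (adjusted p = 0.321 to 0.614 with an estimated correlation) or in fry (smallest adjusted p = 0.207). The matrix and basement membrane list had the smallest p (median -1.06, 31 of 34 members below 0, adjusted p = 5.41e-24; adjusted p = 0.321 with an estimated correlation). Its median was -0.58 in repeat 1 and -1.52 in repeat 2. Ccn1, Lamc1, Col12a1 and Loxl2 fell with the block and the other 30 did not pass over all genes. Adjusted over the list alone, 18 members fell and 1 rose with the block, and 18 fell without it. Ccn2, a matricellular gene, was at 4.59 ± 0.0524 and 16.8 ± 5.79 CPM (block adjusted p = 0.146), and fell in DESeq2 (adjusted p = 5.95e-06).

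The cell cycle list was shifted by a median of -1.18 with all 27 members below 0 (adjusted p = 1.86e-18; adjusted p = 0.322 with an estimated correlation). The repeats had medians of -0.64 and -1.33 for this list. With the block Cdk1, Bub1b, Ccnb1, Kif11, Kif20a, Cenpe and Cenpf fell and 20 did not pass. With adjustment over the list alone, 22 fell with the block and 5 without. The activity-regulated list was shifted by a median of -0.49, with 27 of 28 members below 0 (adjusted p = 1.86e-18; adjusted p = 0.321 with an estimated correlation). In repeats 1 and 2 the medians were -0.39 and -0.61. Scg2, Rgs2 and Fosl2 fell with the block and 25 did not pass, whereas 17 fell adjusted over the list alone, with or without the block. Fos was at 39.6 ± 7.09 and 62.3 ± 1.84 CPM (block adjusted p = 0.0574) and Bdnf at 42.3 ± 6.74 and 66.0 ± 2.32 CPM (block adjusted p = 0.142). Fos and Bdnf fell in DESeq2 (adjusted p = 0.0140 and 0.0350).

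Integrin and focal adhesion genes were shifted by -0.38 (23 of 25 below 0, adjusted p = 1.97e-08; adjusted p = 0.321 with an estimated correlation). Itgb1 and Itgav fell with the block and 23 did not pass; adjusted over the list alone, 10 fell with the block and 6 without. Fibroblast and mural genes were shifted by -0.72 (adjusted p = 3.64e-07; adjusted p = 0.321 with an estimated correlation). The medians were -0.36 in repeat 1 and -1.26 in repeat 2. Of 20, 1 fell over all genes with the block (Cspg4, a proteoglycan of pericytes and oligodendrocyte precursors, to 0.917 ± 0.0350 from 4.95 ± 1.64 CPM), and 6 fell adjusted over the list alone (1 without the block). Mgp was near 0, at 0.0319 and 0 CPM in PA + PS2 and 0.328 and 1.40 CPM in the control. In the neurotrophin and MAPK list (-0.37, adjusted p = 1.29e-06; adjusted p = 0.322 with an estimated correlation), Dusp4, a MAPK phosphatase, and Igf1 fell with the block and 18 did not pass. Adjusted over the list alone, 9 fell with the block and 0 without.

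Markers of other cell types moved with these groups. The progenitor list was shifted by -0.42 (adjusted p = 5.12e-05; adjusted p = 0.441 with an estimated correlation), and Nes, an intermediate filament of progenitors, fell with the block to 22.8 ± 3.56 from 57.3 ± 27.3 CPM, as did Notch1. Of 17, 6 fell with the block and 1 without when adjusted over the list alone. The reactive astrocyte list was shifted by -0.49 (adjusted p = 6.50e-05; adjusted p = 0.321 with an estimated correlation), with Emp1 and Cd44 fallen, 18 not passed, and 8 fallen and 1 risen adjusted over the list alone with the block (5 fallen without it). Astrocyte genes (median -0.51) were shifted with the block (adjusted p = 0.0150) and not without it (0.147), and inflammatory genes likewise (0.0394 and 0.0624, with Vcam1 fallen). Neither kept its block call with an estimated correlation (adjusted p = 0.620 and 0.366 with an estimated correlation). Adjusted over the list alone, 5 astrocyte genes fell and 1 rose with the block and 0 passed without it. The oligodendrocyte list was not shifted (-0.01), yet Mag, Mobp and Cldn11 were among the members that rose and Cspg4 fell with the block, and 10 did not pass. With adjustment over the list alone, 5 rose and 4 fell with the block, and 5 and 1 without it. Mag was at 2.87 and 5.13 CPM in PA + PS2 and 0 and 0.387 in the control, Mobp at 2.30 and 4.22 against 0 and 0.149, and Cldn11 at 0.924 and 1.46 against 0.0298 and 0.149.

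Upward shifts were called for immature neuron genes (0.10, adjusted p = 0.000256; adjusted p = 0.338 with an estimated correlation), cholesterol biosynthesis (0.11), cortical projection neuron genes (0.13), p53 targets (0.21) and ribosomal proteins (0.07). No member of these passed over all genes in edgeR. Adjusted over the list alone with the block, 6 immature neuron genes rose (Draxin, Neurod6, Neurod2, Cd24a, Sox11 and Sox4). Neurod6, a projection neuron transcription factor, was at 399 ± 12.8 and 327 ± 18.5 CPM. Downward shifts were also called for mitochondrially encoded mRNA (-0.37), histone and structured RNA (-0.52, with Lars2 fallen with the block), injury genes (-0.30) and the unfolded protein and integrated stress response (-0.10). Others were perineuronal matrix (-0.24), endothelial (-0.51), postsynaptic (-0.09), interferon (-0.35), glycolysis (-0.11) and presynaptic genes (-0.05, adjusted p = 0.0487). In the stress response list no member passed over all genes, and 7 fell adjusted over the list alone with the block and 4 without; Hspa5, an endoplasmic reticulum chaperone, was at 353 ± 41.6 and 440 ± 2.33 CPM. With the block and adjustment over the list alone, 2 injury genes rose and 6 fell, and 2 interferon, 3 perineuronal matrix and 2 endothelial genes fell. Each of these 15 lists had an adjusted p of 0.321 to 0.614 with an estimated correlation.

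All 23 lists kept their shift without PA 1 or PA 2, 18 without PA + PS2 1, 15 without control 1, 15 without PA + PS2 2 and 16 without control 2. In every one of these cases 7 did, namely matrix, cell cycle, activity-regulated, integrin, fibroblast, neurotrophin and MAPK, and reactive astrocyte genes. Without PA + PS2 2 the presynaptic, postsynaptic, endothelial, perineuronal matrix, glycolysis, mitochondrial, ribosomal and p53 lists lost it, and without control 1 the presynaptic, immature neuron, projection neuron, endothelial, cholesterol, mitochondrial, ribosomal and p53 lists. Without control 2 the presynaptic, postsynaptic, progenitor, endothelial, glycolysis, injury and interferon lists lost it, and without PA + PS2 1 the progenitor, endothelial, cholesterol, histone and stress response lists. The p53 list had a median of 0.03 in repeat 1 and 0.33 in repeat 2, and the ribosomal list 0.01 and 0.15. Not shifted were ion channels (-0.05), neuronal cytoskeleton (-0.02), inhibitory interneuron genes (0.05), oxidative phosphorylation (-0.01), lysosome (0.03), heat shock (-0.13), TGF-beta, BMP and Wnt targets (-0.15), microglia (0.09) and choroid plexus genes (0.05). In the choroid plexus list Ttr, transthyretin, rose with the block, at 23.6 and 0.617 CPM in PA + PS2 1 and 2 and 10.3 and 0.0298 CPM in control 1 and 2.

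**Figure D3:**
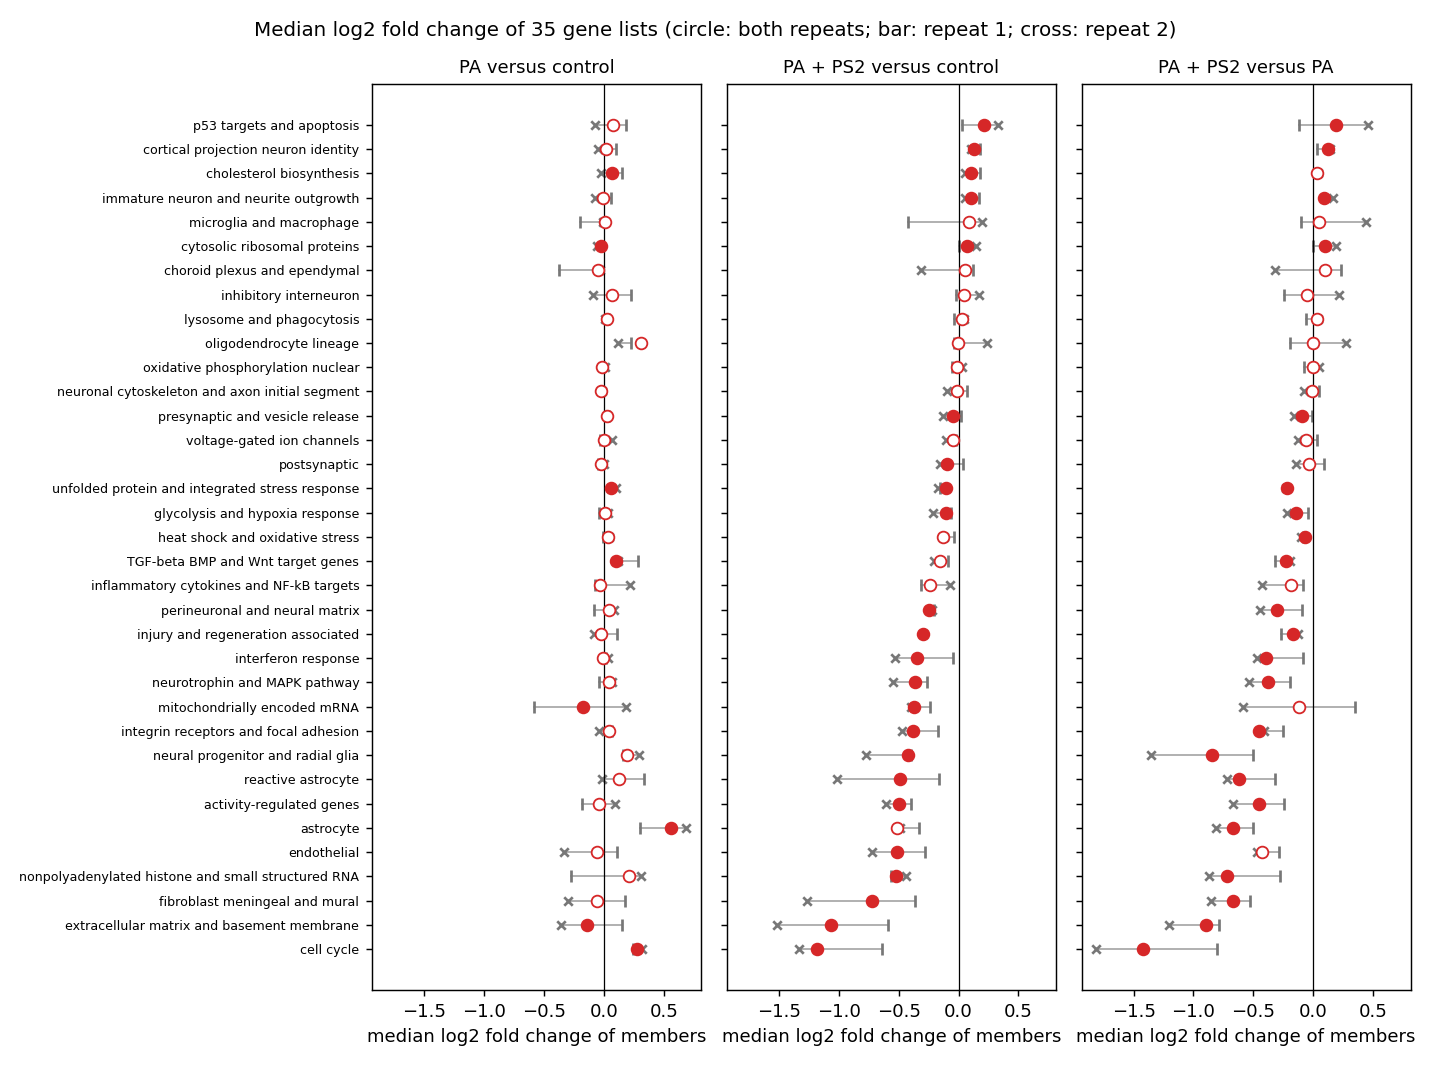
Median log2 fold change over the members of each of the 35 lists in the 3 comparisons (circle both repeats, bar repeat 1, cross repeat 2; filled circles have a camera adjusted p under 0.05 with the preset correlation, and none has with an estimated correlation). The matrix list lies at -1.06 and the cell cycle list at -1.18 in PA + PS2 versus control, and at -0.14 and 0.28 in PA versus control.

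Against PA, 15 of 27 cell cycle, 5 of 34 matrix, 5 of 25 integrin and focal adhesion, 5 of 28 activity-regulated and 7 of 19 astrocyte genes fell in PA + PS2 with the block, and 0 without it in edgeR. The camera shifts of these 5 lists were lost with an estimated correlation (adjusted p = 0.342 to 0.422 with an estimated correlation). With the block, Top2a, a topoisomerase of dividing cells, fell to 9.93 ± 0.474 CPM (SD, n = 2) from 42.6 ± 24.7 (edgeR adjusted p = 0.0209), and Cdk1 to 1.67 ± 0.0224 from 8.81 ± 4.15 CPM. Aldh1l1, an astrocyte folate enzyme, fell to 2.62 ± 0.215 from 16.4 ± 12.8 CPM, and Fos to 39.6 ± 7.09 from 65.4 ± 8.72 CPM. Itgb1 fell to 83.4 ± 0.0701 from 125 ± 5.85 CPM.

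Without the block edgeR called 0 genes between PA + PS2 and PA (smallest adjusted p = 0.360), with 1314 at unadjusted p under 0.05 where 865 are expected. The block called 280 (39 higher and 241 lower), DESeq2 200 (26 and 174, of which 157 shared with the block), and limma-voom and the legacy test 0. The block called 153 with only the 2 groups compared and 364 in DESeq2. With the block 0 genes passed without PA + PS2 2, 96 without PA 2, 102 without control 2, 132 without control 1, 608 without PA + PS2 1 and 626 without PA 1. Among the genes ranked by fold change, Fst (46.9 ± 6.63 from 22.3 ± 6.36 CPM), Fam19a1, Tmtc1, Grik4, Adra2a, Slc16a6 and Nos1 rose with the block. Rfx4, Kcnj10, Epas1, Tead2 and Dock1 fell, Rfx4 with a block log2 fold change of -2.83 and an SE of 0.49. Adamts1, Ptpn14, Gdf10, Ddr2 and Jam2, among the genes with the smallest p without the block in edgeR, did not pass there but passed with the block and in DESeq2 without it. Gdf10, a TGF-beta family ligand, fell with the block to 14.1 ± 0.699 from 26.0 ± 2.02 CPM. Map2 (2260 ± 0.0631 and 2278 ± 160 CPM), Tubb3, Rbfox3, Syn1, Dlg4 and Gfap did not pass, and Bdnf was at 42.3 ± 6.74 and 67.7 ± 13.6 CPM (block adjusted p = 0.0973) and fell in DESeq2 (adjusted p = 0.0146).

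Of the 35 lists, 22 were shifted between PA + PS2 and PA, 4 upwards and 18 downwards. None kept its call with an estimated correlation (adjusted p = 0.342 to 0.554 with an estimated correlation) or in fry (smallest adjusted p = 0.191). The cell cycle list had a median of -1.43 with all 27 members below 0 (adjusted p = 1.80e-23; adjusted p = 0.353 with an estimated correlation). Its median was -0.81 in repeat 1 and -1.81 in repeat 2. With the block 15 members fell and 12 did not pass; adjusted over the list alone, 25 fell with the block and 16 without. Matrix genes had a median of -0.89 (30 of 34 below 0, adjusted p = 1.04e-17; adjusted p = 0.346 with an estimated correlation). The repeats had medians of -0.79 and -1.21. With the block 5 fell, Ccn1, Col12a1, Lamc1, Lamb2 and Fbln2 (0.593 ± 0.333 from 6.34 ± 3.26 CPM), and 29 did not pass; adjusted over the list alone, 13 fell with the block and 12 without. Activity-regulated genes had a median of -0.46 (26 of 28 below 0, adjusted p = 4.55e-14; adjusted p = 0.342 with an estimated correlation). The medians were -0.25 in repeat 1 and -0.67 in repeat 2. Fos, Scg2, Nr4a1, Rgs2 and Fosl2 fell with the block and 23 did not pass, and adjusted over the list alone 14 fell with the block and 10 without.

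Integrin genes had a median of -0.45 (adjusted p = 5.62e-08; adjusted p = 0.342 with an estimated correlation), with Itgb1, Itgav, Itgb8, Itgb5 and Itga6 fallen with the block and 20 not passed; adjusted over the list alone, 11 fell with the block and 6 without. Fibroblast genes had a median of -0.67 (adjusted p = 9.38e-07; adjusted p = 0.342 with an estimated correlation), with Cspg4, Rgs5, Pdgfrb and Mgp fallen, 16 not passed, and 5 fallen with the block and 4 without adjusted over the list alone. Progenitor genes had a median of -0.85 (adjusted p = 9.38e-07; adjusted p = 0.406 with an estimated correlation). Nes (22.8 ± 3.56 from 65.5 ± 31.1 CPM), Notch1 and Vim (144 ± 0.930 from 203 ± 17.4 CPM) fell, 14 did not pass, and 9 fell with the block and 0 without adjusted over the list alone. Astrocyte genes had a median of -0.67 (adjusted p = 0.000238; adjusted p = 0.422 with an estimated correlation). Aldh1l1, Aqp4, Aldoc, Mlc1, Gja1, Sox9 and Clu fell with the block and 12 did not pass, and adjusted over the list alone 11 fell and 1 rose with the block and 2 fell without. The astrocyte call was lost without PA 2, whose median list level was 0.93 against -0.05 in PA 1. Controls 2 and 1 had levels of 0.33 and -0.24, so part of that gap went with the repeat number.

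In the unfolded protein and integrated stress response list (-0.22, adjusted p = 1.78e-06; adjusted p = 0.342 with an estimated correlation), Hspa5, Hsp90b1, Psat1 and Phgdh fell with the block and 18 did not pass; Hspa5 fell to 353 ± 41.6 from 454 ± 8.73 CPM. Neurotrophin and MAPK genes (-0.37, with Spry4, Igf1, Dusp4 and Etv4 fallen) and reactive astrocyte genes (-0.62, with Cd44, Emp1, Cd109 and Vim fallen) were also shifted, with 16 members of each list not passed (adjusted p = 0.353 and 0.342 with an estimated correlation). When adjusted over the list alone, 8, 7 and 7 members of these 3 lists fell with the block, and 7, 4 and 6 without. The 4 upward shifts were in immature neuron genes (0.09, Draxin risen with the block), ribosomal proteins (0.10), p53 targets (0.19) and cortical projection neuron genes (0.12). The p53 list had a median of -0.12 in repeat 1 and 0.46 in repeat 2, and the ribosomal list -0.00 and 0.19. Downward shifts were also called for perineuronal matrix (-0.30), presynaptic (-0.09), injury (-0.17), interferon (-0.39), glycolysis (-0.15), histone and structured RNA (-0.72) and heat shock genes (-0.07). Of these, Ifitm3 and Mt1, a metallothionein, fell with the block. With adjustment over the list alone and the block, 6 immature neuron and 2 projection neuron genes rose, 2 glycolysis genes rose and 4 fell, and 3 interferon and 3 perineuronal matrix genes fell. TGF-beta, BMP and Wnt targets (-0.23) lost their call with the block (block adjusted p = 0.0505). Each of these 12 lists had an adjusted p of 0.342 to 0.554 with an estimated correlation. In the unshifted oligodendrocyte list (0.00), Mag and Mobp were among the members that rose, Cspg4 fell and 11 did not pass with the block; endothelial (-0.43), postsynaptic (-0.04), ion channel (-0.06) and neuronal cytoskeleton genes (-0.01) were not shifted either. In other unshifted lists Gad1, for GABA synthesis, fell with the block to 289 ± 25.2 from 357 ± 52.1 CPM (adjusted p = 0.0492), Vcam1 and Abca1 fell, and Ttr rose. Of the 22 lists, 18 kept their shift without PA + PS2 1, 18 without PA + PS2 2, 15 without PA 2 and 22 without PA 1, control 1 or control 2, and 12 did in each case. Lost without PA 2 were the presynaptic, astrocyte, perineuronal matrix, glycolysis, histone, heat shock and p53 lists. Lost without PA + PS2 2 were the presynaptic, glycolysis, ribosomal and p53 lists, and without PA + PS2 1 the histone, heat shock, injury and TGF-beta lists.

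Both comparisons of PA + PS2 use the same PA + PS2 libraries. With the block, 22 genes rose and 82 fell in both, where independent lists of these lengths share 0.0541 and 1.30. In 50 simulations of unchanged groups, 1.52 genes on average and at most 5 were called in both in the same direction, against 104 observed. Without the block, the log2 fold changes of the 2 comparisons correlated at 0.87 across 13641 genes, which are not independent replicates, against 0.49 simulated, with a covariance of 0.103 against 0.0474. PA and PA + PS2, each against the control, correlated at 0.10 against 0.50 simulated, with a covariance of 0.00589 against 0.0482. Both lay below the lowest simulated values (0.446 and 0.0413), and with the block the covariance of 0.00645 lay below the lowest of 0.0250. The simulations thus gave more shared variation than these comparisons showed. They are therefore not a calibrated reference, also for the pair that shares PA + PS2. With the block in edgeR 0 genes were called in both, PA against control having 0 calls (323 genes at unadjusted p under 0.05), where the simulation gave 1.58 on average. DESeq2 with the block called 1 gene for PA against control, Lars2, which fell in both, where independent lists share 0.0170; without the block DESeq2 called 0. With 2 libraries in a group the shared libraries could not be split, so part of an excess may come from them.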

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

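Between PA and control 0 genes passed in edgeR, DESeq2, limma-voom, the legacy test and the fit with the repeat block. Without the block the count of 0 for every comparison also held with RLE factors, library totals alone, no filter, a stricter filter, limma-voom, the legacy test, only the 2 groups compared and a minimum absolute log2 fold change of 1. Leaving out each library gave 0 to 7 genes for PA + PS2 versus control (7 without PA + PS2 1, 6 higher and 1 lower) and 0 for the others. DESeq2 called 130 genes for PA + PS2 versus control and 200 for PA + PS2 versus PA; the cause was not tested. Of 136 named-gene results, none of which had passed, 70 passed with the block and 63 in DESeq2. Some of these genes were named because they passed with the block, so the count of 70 is partly given by that choice. There were 45 sign changes of uncalled genes that were smaller than their standard error.

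With the block for the pairing, 117 and 280 genes passed for PA + PS2 versus control and versus PA. The tests that combine the block with another choice were added after seeing the data. The block in DESeq2 called 1, 279 and 364 genes in the 3 comparisons (PA versus control, PA + PS2 versus control, PA + PS2 versus PA). The block gave 121 and 258 for the last 2 comparisons with limma-voom, 105 and 266 with RLE, and 42 and 188 with the stricter filter, which tests fewer genes. Only the 2 groups compared, it gave 8, 849 and 153. Leaving out 1 library with the block gave 0 to 12 for PA versus control (10 without PA 1, 12 without PA 2). For PA + PS2 versus control it gave 0 to 560: 503 without PA 1, 522 without PA + PS2 1, 61 without control 1, 560 without PA 2, and 0 without PA + PS2 2 or control 2. For PA + PS2 versus PA it gave 0 to 626: 626 without PA 1, 608 without PA + PS2 1, 132 without control 1, 96 without PA 2, 0 without PA + PS2 2 and 102 without control 2. The cause was not tested, and a group left with 1 library was assumed to vary like the others. For counts over all genes and shifts of lists, besides those printed with the report's results, the block changed no other call; some counts adjusted over a list alone changed with it and are not all printed.

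Of 35 lists, 8, 23 and 22 were shifted in the 3 comparisons, and 9, 25 and 21 with the block. The stricter filter ended 2 calls in PA + PS2 versus PA, the histone and structured RNA and heat shock lists (20 of 22 kept); the cause was not tested. With an estimated correlation 0, 0 and 0 were, and the same 0 in each with the block added. Fry called 0, 0 and 0, and 1, 0 and 0 with the block; the cause was not tested. Leaving out each library gave 3 to 11 lists for PA versus control (3 without control 1, 11 without PA 2), 16 to 26 for PA + PS2 versus control and 18 to 24 for PA + PS2 versus PA. Depth limits genes under 1 CPM most, where the median standard error of a log2 fold change was 0.64 to 0.66 in the 3 comparisons.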

Other observations

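The tests of other cell types, of 1 library alone, of fewer neurons and of pseudogenes below were chosen only after the result was seen. Medians over both repeats in those tests come from the fit with the repeat block. Genes of the oligodendrocyte lineage went both ways in PA + PS2, and these were picked after their values were seen. Mbp, a myelin protein, was at 32.4 and 53.6 CPM in PA + PS2 1 and 2, 26.1 and 24.5 in PA, and 21.7 ± 0.419 (SD, n = 2) in the control (block adjusted p = 0.0726 against the control), and it rose in DESeq2 (adjusted p = 0.00426 for Mbp). Olig1, a transcription factor of the lineage, was at 2.45 and 2.37 CPM in PA + PS2, 12.5 and 37.9 in the control and 9.75 and 59.6 in PA (block adjusted p = 0.257). Olig2 was at 2.07 and 1.40 CPM in PA + PS2, 8.49 and 22.6 in the control and 6.14 and 34.7 in PA (block adjusted p = 0.274). Pdgfra, a receptor of precursors and fibroblasts, was at 2.04 and 0.975 CPM in PA + PS2 and 7.30 and 11.9 in the control (block adjusted p = 0.463).

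A few p53 targets stood apart in PA + PS2 2. Bbc3, which promotes apoptosis, was at 61.2 CPM there and at 16.0 to 23.8 CPM in the other 5 libraries, and Phlda3 at 25.4 against 5.77 to 7.82 CPM. The median level of the p53 list relative to all libraries was 0.36 in PA + PS2 2 and -0.17 in PA + PS2 1. Between the repeat numbers 901 genes differed in edgeR, 373 higher and 528 lower in repeat 2. Tuba1c, a tubulin, was at 37.3 to 47.4 CPM in repeat 1 and 132 to 149 in repeat 2, and Slc7a11, a cystine transporter, at 15.8 to 19.4 and 55.6 to 59.1 CPM. Cacna1b, a calcium channel subunit, was at 392 to 434 CPM in repeat 1 and 211 to 224 in repeat 2. Xist, expressed from the inactive X, was at 988 to 1141 and 644 to 724 CPM, and the Y-linked Ddx3y at 16.9 to 18.5 and 36.2 to 39.5 CPM.

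The matrix, fibroblast and cell cycle lists were shifted downwards in PA + PS2 against the control, without keeping the call with an estimated correlation. In repeat 1 the matrix, fibroblast and cell cycle medians were -0.58, -0.36 and -0.64, below random lists (-0.09, -0.25 and -0.15). These lists were thus lower in PA + PS2 1 as well. Random lists lack the correlation within these lists, estimated at 0.44, 0.08 and 0.83, so their bounds are not the spread between libraries. In PA versus control, with 0 edgeR calls, the 3 medians were 0.15, 0.18 and 0.24 in repeat 1 and -0.35, -0.30 and 0.32 in repeat 2. Members lower in PA + PS2 than in the control in both repeats were 30 of 34 (matrix), 15 of 20 (fibroblast) and 26 of 27 (cell cycle). The direction of the pattern thus does not rest on PA + PS2 2 alone. Whether the shift in repeat 1 exceeds the spread between libraries is not decided. For the matrix list, GC content and length were argued against as the whole cause, since its median was -1.09 before and -1.02 after their trend was removed. The fibroblast and cell cycle lists were not tested for this. Fewer non-neuronal cells of every type alike stay open: the microglia median lay 0.870 above the fibroblast median (random upper 0.375), the largest of 6 such gaps, of which the endothelial one (0.262) was inside its bound, but in repeat 1 the microglia gap was -0.06 and no list passed its bound. The bounds of this test were rewritten after the list medians were seen, and the difference between the groups and culture batches that follow the groups also stay open and untested.

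The activity-regulated list was shifted downwards in PA + PS2 against the control, and lost the call with an estimated correlation. The 9 members taken as neuron-restricted (Arc, Npas4, Bdnf, Nptx2, Vgf, Scg2, Pcsk1, Nrn1 and Homer1) had medians of -0.45 in repeat 1 and -0.78 in repeat 2. These lay below random lists (-0.10 and -0.13). They argue against loss of other cells that express immediate early genes as the whole cause only if the 9 are neuron-restricted, which was not tested. The 9 belong to the list already seen to be lower, and random lists lack its correlation, estimated at 0.29. In PA versus control the whole list had medians of -0.18 in repeat 1 and 0.09 in repeat 2. Fewer neurons in the library were argued against as the whole cause of the lower activity list. The neuronal cytoskeleton median lay 0.231 above 0.5 times that of the activity genes, beyond the 0.0747 of random lists. Scaled counts do not give the number of neurons itself. Random lists lack the correlation within the lists here as well. Handling before lysis, which the labels do not describe, and the difference between the groups stay open and untested.

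Genes differed between the repeat numbers in all 3 groups, and Rps2-ps13, a pseudogene on chromosome X (52898588 to 52899469), was at 49.8 to 56.7 CPM in repeat 1 and 0.238 to 0.325 in repeat 2. Genotype of the outbred mice with reads split between near-identical copies could not be told apart from other causes: pseudogenes were 5.07% called against 5.22% of other genes, an odds ratio of 0.970 (95% interval 0.737 to 1.26). A form within 10 classes of expression, added after that ratio was seen, gave 1.92 (1.44 to 2.55), so the 2 forms differ and neither decides. GC content and length between batches were argued against by rank correlations of -0.0101 and -0.0225 over 17287 genes. Xist was lower and the Y-linked Ddx3y and Eif2s3y were higher in repeat 2 in all 3 groups, as a different mix of sexes would give. Eif2s3y was at 15.0, 15.0 and 15.1 CPM in repeat 1 of PA, PA + PS2 and control, and at 29.4, 30.2 and 27.1 CPM in repeat 2. How far sex accounts for the other genes was not tested, nor were other biological differences between the repeats.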
